A study of Oryza sativa with 10 samples.

How the data were processed

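RNA was measured in developing rice (Oryza sativa) seeds without the husk. The labels give 5 genotypes at 48 and 72 hours after fertilization (HAF), with 1 library for each genotype and time and 10 libraries in all. Per the labels' protocols, RNA was isolated with an RNeasy Plant mini kit and libraries followed standard Illumina protocols. Each library's deposited values are counts, meaning whole numbers of reads per gene with no normalization, for 55801 features with identifiers of the LOC_Os form. TopHat2 and HTSeq are named, per the submitters' processing notes, with no version. The genome build, annotation release, read filters and strand setting are not given in the sources used here. Reads of close paralogs and of overlapping or antisense genes may therefore be split or merged in ways that cannot be resolved here. The glutelin genes and neighbouring gene copies are among the genes this can concern. Library totals ran from 12267337 counts in the CR79 72 HAF library to 18040600 in the WT 72 HAF library.

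Genes were kept with the edgeR filter for low counts at a minimum count of 10, which left 25354 genes. A further 15472 features had no read in any library. Libraries were scaled by TMM, and expression values are CPM, the deposited counts divided by the TMM-scaled library total. Tests used the quasi-likelihood method of edgeR 4.0.16 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The time effect, each line against WT and overexpression against CRISPR came from 1 additive fit of genotype and time over all 10 libraries, with 4 residual degrees of freedom and a biological coefficient of variation of 20.7%. The class by time interaction came from a fit with a mean for each class (WT, overexpression, CRISPR) at each time, also with 4 residual degrees of freedom and a coefficient of variation of 21.7%. In that fit the 2 lines of a class served as its replicates. The libraries are paired by line, as the labels give each line at both times. Deviations from the mean of each time correlated between the libraries of a line at 0.314 in WT, 0.065 in OE78, 0.328 in OE79, 0.106 in CR78 and 0.312 in CR79. The additive fit uses this pairing. The class by time fit does not, so the interaction was also fitted with the line as a block, which gave 1018 genes against 3. The block fit has fewer residual degrees of freedom than the other fits, since both WT libraries are fitted exactly and each class keeps 1 comparison of its lines. It was not among the tests run on simulated data. Contrasts within 1 time from the same fit were added after the data were seen.

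No genotype was sampled more than once at a time, and 1 line stood for each manipulation. The p-values therefore measure only the spread between these libraries, and they cannot separate a manipulated gene from other differences of its line. Those of the additive fit assume that genotype and time effects add. Their spread is the departure of the genotypes from a common time effect. For each line against WT and for overexpression against CRISPR, the 2 times of a line thus stand in for replicates. Spread between the lines of a class is left out of these tests. A cell of 1 library against 1 was given as values with no test. Where a run that leaves out libraries leaves an arm with 1, that library is assumed to vary like the other groups, and the same holds for WT within 72 HAF.

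Gene lists, each pairing a gene name with a locus identifier as published for rice, were fixed together with the main tests, the main alternatives and the rule for named genes before the data were examined. The lists cover the targeted genes, other type I MADS genes, type II MADS genes of flower and seed, starch synthesis, sucrose cleavage, seed storage proteins, endosperm transcription factors, chromatin, DNA replication and cell cycle, cell wall synthases, auxin synthesis, the gibberellin pathway, abscisic acid turnover, alpha-amylases, photosynthesis (green pericarp markers), embryo and shoot meristem markers, anther and tapetum markers, and heat shock. None of the identifiers stands in the RefSeq gene table used here. Names were instead checked by whether the named RefSeq gene lies at the place that its neighbours in identifier order give, within 2 Mb. Of 176 pairs, 109 passed that check, 62 names were missing from the table, 3 were contradicted and dropped, and 2 identifiers were absent, so 171 pairs were used. List counts use all of these, while the text names only pairs that passed, together with MADS78 and MADS79, whose pairing rests on the published identifier. No coordinates are given, because the build of the identifiers is not stated.

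The rule for named genes takes MADS78 and MADS79 in every library. From each list it takes up to 4 members with the smallest adjusted p among those past the threshold, or up to 2 of the most abundant where none passed. It also takes the genes with the largest changes that have a mean CPM of at least 5 and 1 direction in every pair. Of these last genes, at most 2 identifiers that rose and 2 that fell are printed per comparison, because they carry no name. Genes named outside the rule are said to have been chosen after their values were seen.

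Lists with at least 3 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation, with adjustment over lists within a contrast. Counts adjusted over the list alone are given beside those over all genes. A stage index was the mean log2 CPM (prior count 2) of the 200 genes with the largest rise from WT 48 to WT 72 HAF minus that of the 200 with the largest fall. Its genes had a mean CPM of at least 10 in WT. They were chosen without the 8 mutant libraries, so only the WT values of the index are not independent of the choice. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

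Alternatives were DESeq2 size factors, no filter beyond 1 read, the DESeq2 1.42.0 Wald test, limma-voom, a minimum change of 2-fold, leaving out the 50 most abundant genes, and leaving out each library in turn. Other model designs, and other settings of the correlation and the stage index, were also run.

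The tests were tested on simulated data with the real means and library sizes of the 25354 genes, of which 100 were changed 2-fold and 100 4-fold. For the time effect, 58% of the 2-fold and 87% of the 4-fold changes were recovered, and 9.38% of calls were false. Recovery was 51% and 84% for overexpression against CRISPR, with 10% false calls, and 18% and 67% for CR79 against WT, with 9.57% false calls. It was 20% and 61% for overexpression against CRISPR at 72 HAF, with 5.81% false calls, and 3% and 39% for the interaction, with 12.5% false calls. These rates hold for the simulated setting, in which far fewer genes changed than the 28.1% called for time. Its match to the real spread between lines was not checked. The class by time fit takes lines as replicates, so its rates may be too favourable.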

Results

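The study sequenced RNA of rice seeds collected 48 and 72 hours after fertilization (HAF), when the endosperm is passing from free nuclei to walled cells. MADS78 and MADS79 are type I MADS-box transcription factor genes, and the study asked about their part in early seed development. Wild type (WT) was compared with 1 line labelled as overexpressing MADS78 (OE78-8, here OE78), 1 as overexpressing MADS79 (OE79-3, here OE79), 1 as edited by CRISPR at MADS78 (Cr78_8.22.2, here CR78) and 1 as edited at MADS79 (Cr79_11.25.3, here CR79). Each of the 5 genotypes gave 1 library at each time, so no value at a single time has a replicate. Depth lay between 15349522 and 18040600 counts in 9 libraries and was 12267337 in CR79 72 HAF, and 29352 to 31278 genes were detected. The 50 most abundant genes took 15.1% of the counts in CR79 72 HAF, against 6.8% to 9.28% in the other libraries.

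The targeted genes were read first. MADS78 (LOC_Os09g02830) had 2116 reads, or 138 CPM, in the OE78 72 HAF library and 6 reads in the OE78 48 HAF library, against 3 and 0 in WT. The remaining libraries had 0 to 6 reads of it. MADS79 (LOC_Os01g74440) had 33 and 20 reads in WT at 48 and 72 HAF and 39 and 7 in the libraries labelled OE79, so its reads were not raised there. In the CRISPR lines MADS79 had 36 and 3 reads in CR78 and 34 and 0 in CR79, and MADS78 had at most 1 read. WT levels of both genes were too low for the counts to check the CRISPR labels, and an edited gene can still be transcribed. MADS79 fell with time over the genotypes (log2 fold change -2.74, edgeR adjusted p = 0.0205). OE79 and OE78 48 HAF therefore name libraries labelled so, in which the reads at the targeted locus were not raised. Counts at the locus would not show a transgene that lacks the counted region, so they do not settle whether MADS79 was raised in OE79.

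**Figure D1:**
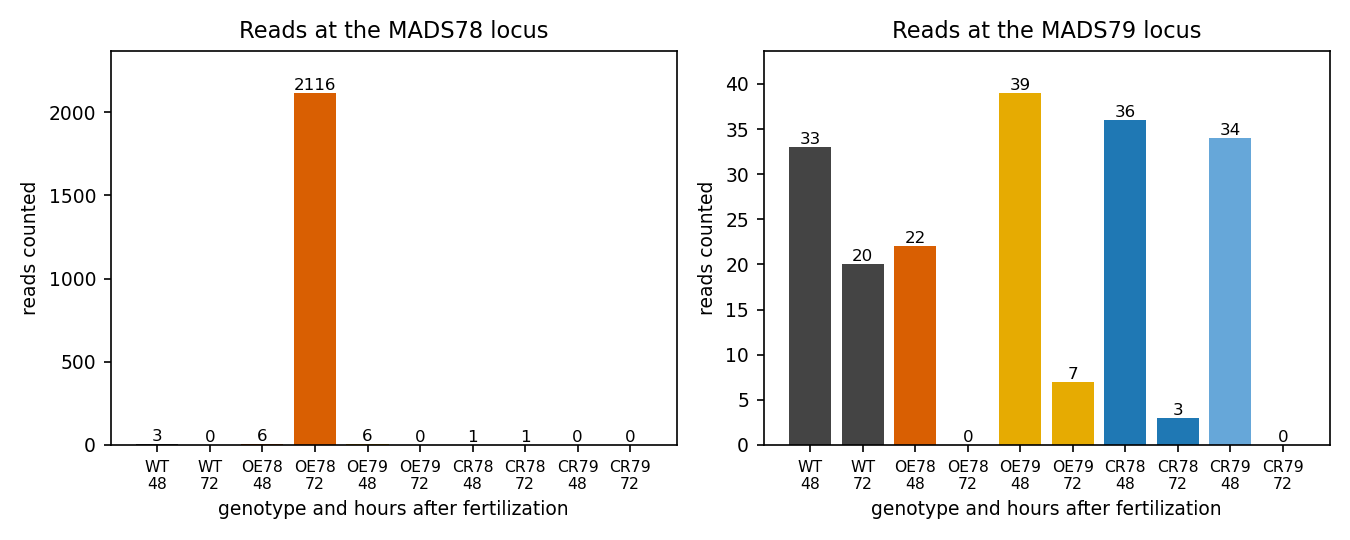
Reads counted at the MADS78 and the MADS79 locus (vertical axes) in each of the 10 libraries (horizontal axes, genotype and hours after fertilization). MADS78 reached 2116 reads in the OE78 72 HAF library and at most 6 elsewhere, and MADS79 did not exceed 39 reads.

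From 48 to 72 HAF, most genes for starch synthesis and the endosperm regulators rose, by a test of 1 time effect over the 5 genotypes. Of 27 starch synthesis genes, 18 rose, 2 fell and 7 did not pass (19 and 3 when adjusted over the list alone), with a median log2 fold change of 0.66 (camera in limma, adjusted p = 3.88e-07). That list test gave adjusted p = 0.263 with an estimated correlation. Wx (LOC_Os06g04200), the granule-bound starch synthase that makes amylose, lay at or below 0.292 CPM in every 48 HAF library and between 36.8 and 646 CPM at 72 HAF (edgeR adjusted p = 1.66e-05). SSIIa (LOC_Os06g12450), a soluble starch synthase, rose by a log2 fold change of 5.38 (SE 0.466, edgeR adjusted p = 0.000154). The debranching enzyme gene ISA1 (LOC_Os08g40930) rose by 2.29 (SE 0.274, edgeR adjusted p = 0.000712), and AGPS2 (LOC_Os08g25734), for an ADP-glucose pyrophosphorylase subunit, by 1.57 (SE 0.311, edgeR adjusted p = 0.00728). The members that fell were the soluble starch synthases SSIIb (LOC_Os02g51070), with a log2 fold change of -0.43, and SSIIc (LOC_Os10g30156), with -0.35. All 6 endosperm transcription factors rose (camera in limma, adjusted p = 9.82e-06, and adjusted p = 0.263 with an estimated correlation), the same 6 when adjusted over the list alone. Among them, NF-YB1 (LOC_Os02g49410) went from at most 0.0574 CPM to between 3.26 and 13.5 CPM (edgeR adjusted p = 4.26e-05).

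Genes of sucrose use and storage also moved. Of 8 sucrose cleavage genes 7 rose and 1 fell, also when adjusted over the list alone (camera in limma, adjusted p = 0.00976, and adjusted p = 0.263 with an estimated correlation). SUS3 (LOC_Os07g42490), a sucrose synthase, rose by a log2 fold change of 2.83 (SE 0.289, edgeR adjusted p = 0.000332). GIF1 (LOC_Os04g33740), a cell wall invertase of the filling grain, rose by 0.67, while the invertase gene CIN1 (LOC_Os02g33110) fell by 1.86 on the log2 scale (SE 0.241, edgeR adjusted p = 0.00101). Of 7 tested storage protein genes 4 rose and 3 did not pass, also when adjusted over the list alone (camera in limma, adjusted p = 0.0419, and adjusted p = 0.438 with an estimated correlation). One of these, LOC_Os03g55730, singled out after its values were seen, stood at 57.5 to 75.9 CPM in all 10 libraries, so its place among seed storage genes is in doubt, and every storage count here includes it. The glutelin gene GluB2 (LOC_Os02g15150) had no read in any 48 HAF library or in WT 72 HAF, and 15.3 and 37.9 CPM in CR78 and CR79 at 72 HAF. All 9 photosynthesis genes, taken as markers of the green pericarp, rose in the same interval (camera in limma, adjusted p = 5.79e-07, and adjusted p = 0.263 with an estimated correlation). Cab2R (LOC_Os01g41710), a chlorophyll-binding protein gene, rose by a log2 fold change of 1.22 (SE 0.173, edgeR adjusted p = 0.00156).

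DNA replication and cell cycle genes fell. Of 16, 15 fell and 1 rose, also when adjusted over the list alone, with a median log2 fold change of -0.88 (camera in limma, adjusted p = 8.62e-10, and adjusted p = 0.0888 with an estimated correlation). MCM3 (LOC_Os05g39850), part of the helicase that opens DNA for replication, fell by 1.23 on the log2 scale (SE 0.074, edgeR adjusted p = 3.37e-05). PCNA (LOC_Os02g56130), the sliding clamp of DNA polymerase, fell by 0.86 (SE 0.074, edgeR adjusted p = 0.00015), and MCM4 (LOC_Os01g36390) fell by 1.11 (SE 0.104, edgeR adjusted p = 0.000226). The gene that rose was KRP1 (LOC_Os02g52480), an inhibitor of cyclin-dependent kinases (log2 fold change 0.72, SE 0.082, edgeR adjusted p = 0.000589).

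**Figure D2:**
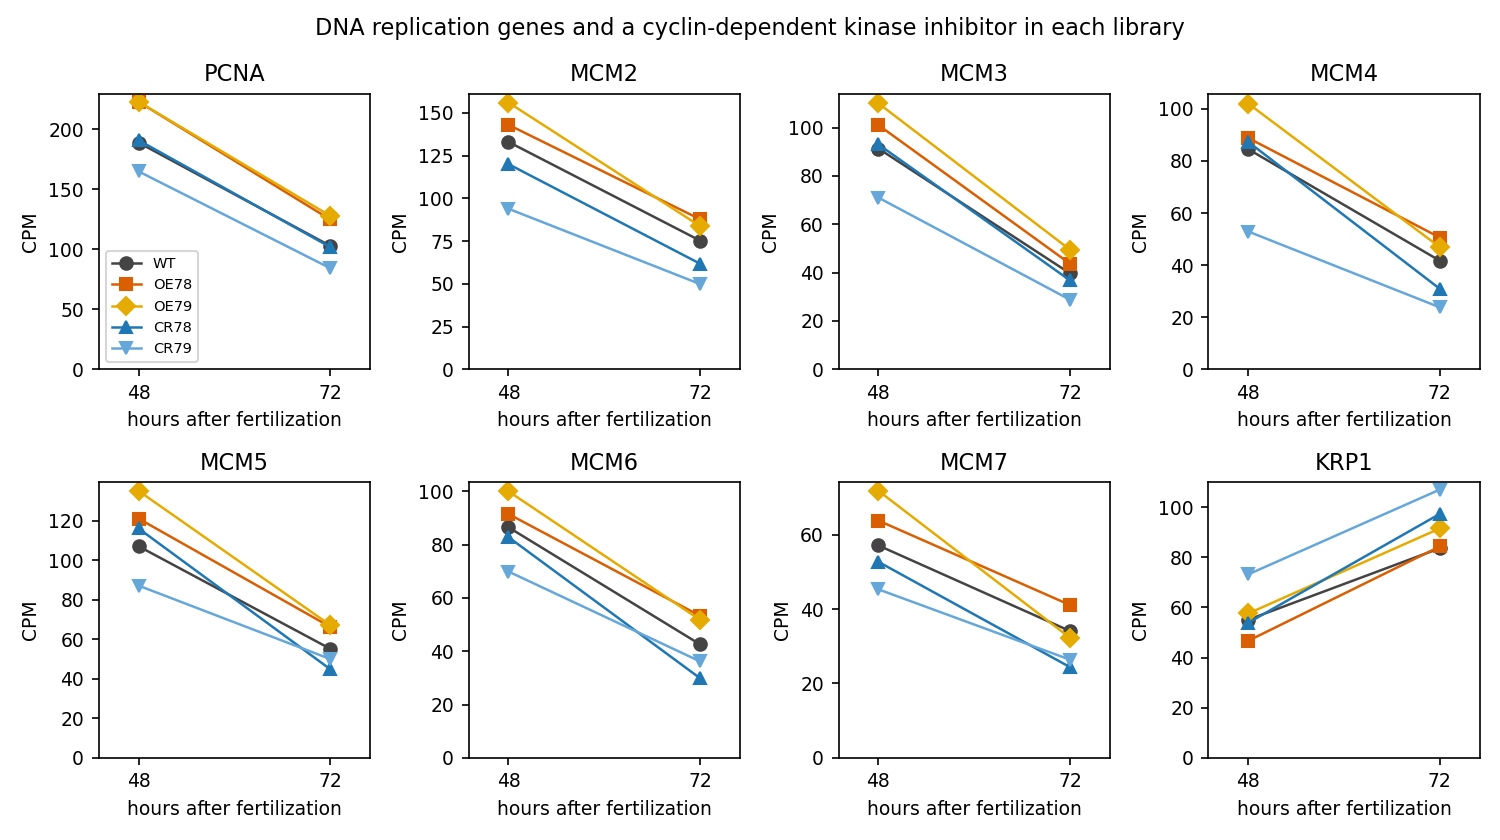
Expression (CPM, vertical axes from 0) of PCNA, MCM2 to MCM7 and KRP1 at 48 and 72 hours after fertilization (horizontal axes), with a line for each genotype. The replication genes are lower and KRP1 is higher at 72 HAF in each of the 5 genotypes.

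Other lists moved in part. Among 13 chromatin genes 2 rose and 4 fell, also when adjusted over the list alone (camera in limma, adjusted p = 0.323), and the DNA methyltransferase genes CMT3a (LOC_Os10g01570) and MET1a (LOC_Os03g58400) fell by 1.22 and 0.73 on the log2 scale. Of 18 type II MADS genes 3 fell and none rose (camera in limma, adjusted p = 0.053), namely MADS17 (LOC_Os04g49150), MADS16 (LOC_Os06g49840) and MADS6 (LOC_Os02g45770), with log2 fold changes of -0.78, -1.52 and -0.52. Of 3 other type I MADS genes 2 fell (camera in limma, adjusted p = 0.053). Of 11 cell wall synthase genes 4 rose (camera in limma, adjusted p = 0.0419, and adjusted p = 0.263 with an estimated correlation). They include the cellulose synthase gene CesA8 (LOC_Os07g10770), at 0.68, and CslF6 (LOC_Os08g06380), which makes mixed-linkage glucan, at 0.90.

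Among hormone genes, 3 of 6 for auxin synthesis rose (camera in limma, adjusted p = 0.0866), with TAA1 (LOC_Os01g07500) at a log2 fold change of 0.38. Of 10 gibberellin genes 2 fell (camera in limma, adjusted p = 0.153), with the biosynthetic oxidase gene GA20ox2 (LOC_Os01g66100) at -1.13. Of 7 genes of abscisic acid turnover 2 fell, or 3 when adjusted over the list alone (camera in limma, adjusted p = 0.053), with NCED3 (LOC_Os03g44380), which acts in abscisic acid synthesis, at -2.46. Of 3 embryo and meristem markers 1 rose and 1 fell (camera in limma, adjusted p = 0.391), the latter being the homeobox gene OSH1 (LOC_Os03g51690) at -1.63. Of 5 anther markers 1 fell (camera in limma, adjusted p = 0.264), GAMYB (LOC_Os01g59660) at -0.29, and of 6 heat shock genes none passed (camera in limma, adjusted p = 0.053). For the type I and type II MADS, cell wall, auxin, gibberellin, embryo, anther and heat shock lists the counts adjusted over the list alone were the same. The alpha-amylase list had too few tested members for a list test. Its RAmy3D (LOC_Os08g36910) stood at 15.7 CPM in WT 72 HAF and at 0.115 to 8.1 CPM elsewhere.

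Over all genes, 7114 of 25354 changed between the times (28.1%), 3843 upward and 3271 downward, and 1256 of them at least 4-fold (edgeR, adjusted p under the threshold of 0.05). The genes with the largest changes carry no name here. LOC_Os07g41290 and LOC_Os01g33370 had no read at 48 HAF in any genotype and reached 6.46 to 181 CPM and 36.4 to 137 CPM at 72 HAF. LOC_Os05g36010 went from between 19.6 and 56.9 CPM to between 0.87 and 12.7 CPM, and LOC_Os01g04290 was lower at 72 HAF in every genotype, from 39.7 to 0.111 CPM in WT. Without the CR78 48 or 72 HAF library the count was 4388 or 4397. Without both the CR78 and OE78 48 HAF libraries, which stand apart for heat shock genes and for MADS78, it was 2388, of which 2360 were shared, in a test with fewer libraries.

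The comparison of OE78 with WT takes both times of the line together, although reads of MADS78 were raised in its 72 HAF library alone. Of the tested genes 34 were higher and 2 lower in OE78 over both times (edgeR), and 1223 had an unadjusted p under 0.05, against 1268 by chance. No list member passed over all genes, and adjusted over the list alone 2 of 6 endosperm transcription factors were higher and 1, with no read at 48 HAF, lower. LOC_Os03g02470 stood at 223 and 190 CPM in OE78 and at 0.059 and 0 in WT, and LOC_Os04g13000 at 45.2 and 23.4 CPM and at 0 in WT. Neither was particular to OE78: LOC_Os03g02470 stood at 158 to 230 CPM in CR78 and CR79, and LOC_Os04g13000 at 7.13 and 6.69 CPM in OE79. LOC_Os05g01300 was lower (log2 fold change -1.35, SE 0.155, edgeR adjusted p = 0.022), as was LOC_Os02g10780, at 3.04 and 2.48 CPM against 13.3 and 16.4. The latter was at 4.97 to 11.5 CPM in OE79, CR78 and CR79. As groups, DNA replication genes were shifted up (median log2 fold change 0.16, camera in limma, adjusted p = 0.00441, and adjusted p = 0.376 with an estimated correlation). Cell wall synthases were shifted down (median -0.21, adjusted p = 0.0104, and adjusted p = 0.376 with an estimated correlation, camera in limma). Type II MADS genes were shifted up (median 0.17, adjusted p = 0.0338, and adjusted p = 0.868 with an estimated correlation, camera in limma). The gene count was 5 without either WT library, 6 without OE78 48 HAF, 14 without OE78 72 HAF, and 16 and 15 without OE79 48 and 72 HAF.

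In the libraries labelled OE79, 37 genes were higher and 2 lower than in WT (edgeR), and 836 had an unadjusted p under 0.05. LOC_Os10g30240 reached 103 and 82.4 CPM against 0 and 0.0557 in WT, and LOC_Os06g44800 reached 14.1 and 7.42 CPM against 0. LOC_Os06g44800 was not particular to OE79, with 35.1 and 16.4 CPM in OE78 and 5.83 and 3.74 CPM in CR79. LOC_Os06g27370 was lower (2.51 and 2.39 CPM against 15.3 and 12.7), as was LOC_Os10g41370 (log2 fold change -1.26, SE 0.169, edgeR adjusted p = 0.0397). No list member passed over all genes, and adjusted over the list alone 1 of 18 type II MADS genes was higher, MADS1 (LOC_Os03g11614). DNA replication genes were shifted up (median log2 fold change 0.17, camera in limma, adjusted p = 0.000174, and adjusted p = 0.337 with an estimated correlation), and so were type II MADS genes (median 0.17, adjusted p = 0.00027, and adjusted p = 0.988 with an estimated correlation). The count was 2 without either WT library and 4 and 7 without OE79 48 and 72 HAF.

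In CR78, 19 genes were higher than in WT and none lower (edgeR), with 1368 at an unadjusted p under 0.05. The endosperm transcription factors were shifted up, with a median log2 fold change of 3.00 (camera in limma, adjusted p = 4.47e-14, and adjusted p = 0.177 with an estimated correlation). Of its 6 members 1 passed over all genes and 6 when adjusted over the list alone. Of these, 4 had at most 2 reads in any 48 HAF library, so their difference from WT rests on 1 library against 1 at 72 HAF and counts as a value without a replicate. Starch synthesis genes had a median of 0.30 with no member past the threshold (camera in limma, adjusted p = 4.66e-06, and adjusted p = 0.463 with an estimated correlation). Of 7 storage protein genes none passed over all genes and 4 did when adjusted over the list alone (camera in limma, adjusted p = 0.000964, and adjusted p = 0.46 with an estimated correlation), with at most 1 read of any of these 4 in any 48 HAF library, so the same holds for them. Heat shock genes were shifted up too (camera in limma, adjusted p = 0.00214, and adjusted p = 0.463 with an estimated correlation), with HSP101 (LOC_Os05g44340) at 144 CPM in CR78 48 HAF and at 9.6 to 18.3 CPM in every other library. Auxin synthesis genes were shifted up and cell wall synthases down, both at adjusted p = 0.0209 (camera in limma), with adjusted p = 0.422 and adjusted p = 0.46 with an estimated correlation, and 1 of 6 auxin synthesis genes was higher when adjusted over the list alone. LOC_Os12g24050 reached 18.4 and 33.4 CPM against 0.118 and 0 in WT, but it stood at 25.1 and 26.4 CPM in OE79 as well. The count was 2 and 3 without WT 48 and 72 HAF, 6 without either CR78 library, 11 without either OE78 library, and 11 and 10 without OE79 48 and 72 HAF.

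CR79 differed from WT in 555 genes, 371 higher and 184 lower (edgeR), with 5518 at an unadjusted p under 0.05. Of 6 endosperm transcription factors 4 were higher, or 6 when adjusted over the list alone (camera in limma, adjusted p = 2.89e-06, and adjusted p = 0.24 with an estimated correlation). Of 7 storage protein genes 2 were higher, or 5 when adjusted over the list alone (camera in limma, adjusted p = 0.00193, and adjusted p = 0.512 with an estimated correlation), GluB2 among them. As in CR78, 4 of the transcription factor genes and 4 of the storage genes had next to no reads at 48 HAF, so their difference from WT rests on 1 library against 1 at 72 HAF and counts as a value without a replicate. MADS1 (LOC_Os03g11614), a floral organ identity gene, was higher (log2 fold change 0.81, SE 0.146, edgeR adjusted p = 0.0357). Of 11 cell wall synthases the cellulose synthase CesA2 (LOC_Os03g59340) was lower (log2 fold change -1.02, SE 0.152, edgeR adjusted p = 0.0246), and the list was shifted down (camera in limma, adjusted p = 0.00177, and adjusted p = 0.24 with an estimated correlation). DNA replication genes had a median of -0.24, with none past the threshold and 1 higher and 4 lower when adjusted over the list alone (camera in limma, adjusted p = 0.00193, and adjusted p = 0.24 with an estimated correlation). Photosynthesis genes had a median of 0.45 (camera in limma, adjusted p = 0.0164, and adjusted p = 0.643 with an estimated correlation). Of 27 starch synthesis genes 1 was lower, or 2 when adjusted over the list alone (camera in limma, adjusted p = 0.875). LOC_Os07g06834 stood at 38 and 26.4 CPM against 0.059 and 0.111 in WT, and LOC_Os02g55970 at 1.96 and 2 against 16.3 and 9.14. The count was 11 and 7 without WT 48 and 72 HAF, 142 and 53 without CR79 48 and 72 HAF, 283 and 239 without those of CR78, 283 and 280 without those of OE78, and 163 without either OE79 library.

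Taken at 1 time, pairs of single libraries give values with no replicate check. Among genes at 5 CPM or more in either library, OE78 had 70 higher and 134 lower by 4-fold or more than WT at 48 HAF, and 59 and 26 at 72 HAF. OE79 had 88 and 34 at 48 HAF and 75 and 4 at 72 HAF. For CR78 the numbers were 74 and 76, then 134 and 56. For CR79 they were 107 and 82, then 213 and 186.

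Setting overexpression against CRISPR lines compares the opposite manipulations of both genes without using WT as the baseline. In 3 of the 4 overexpression libraries the reads counted at the targeted locus were not raised. Over both times the lists of endosperm regulators and storage genes were shifted down and that of DNA replication genes up, with few members past the threshold over all genes, and none of the 3 lists passed with an estimated correlation (adjusted p = 0.15, adjusted p = 0.292 and adjusted p = 0.15). At 48 HAF alone the storage list had a median log2 fold change of 0 (camera in limma, adjusted p = 0.868) and the endosperm transcription factors one of -0.49 (camera in limma, adjusted p = 0.483). All 6 endosperm transcription factors had lower values in the overexpression lines when adjusted over the list alone, and 3 passed over all genes (camera in limma, adjusted p = 1.76e-09, and adjusted p = 0.15 with an estimated correlation). Of 7 storage protein genes 2 were lower, or 6 when adjusted over the list alone (camera in limma, adjusted p = 0.000117, and adjusted p = 0.292 with an estimated correlation). As in the comparisons with WT, 4 of the transcription factor genes and 4 of the storage genes had next to no reads at 48 HAF. Their difference rests on the later time. Of 16 replication genes MCM2 (LOC_Os11g29380) was higher (log2 fold change 0.55, SE 0.084, edgeR adjusted p = 0.0387), and 9 were higher and 1 lower when adjusted over the list alone (camera in limma, adjusted p = 2.98e-06, and adjusted p = 0.15 with an estimated correlation). Of 27 starch synthesis genes Wx was lower (log2 fold change -3.23, SE 0.521, edgeR adjusted p = 0.0452), with 1 higher and 5 lower when adjusted over the list alone (camera in limma, adjusted p = 0.0457, and adjusted p = 0.626 with an estimated correlation). Wx itself had next to no reads at 48 HAF, so its difference rests on the later time. At 48 HAF alone its log2 fold change was 4.52 (SE 2.44, edgeR adjusted p = 0.702). Auxin synthesis genes were shifted down with none past the threshold, or 3 when adjusted over the list alone (camera in limma, adjusted p = 0.00408, and adjusted p = 0.15 with an estimated correlation). Cell wall synthases (adjusted p = 0.0219) and type II MADS genes (adjusted p = 0.0418) were shifted up and photosynthesis genes down (adjusted p = 0.0376) by camera in limma, with no member past the threshold over all genes and 4 type II MADS genes higher and 1 lower when adjusted over the list alone. With an estimated correlation these gave adjusted p = 0.292, adjusted p = 0.609 and adjusted p = 0.609.

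Over all genes, 54 were higher and 91 lower in the overexpression lines (edgeR), with 4580 at an unadjusted p under 0.05. The share of higher genes, 37.2% here, was 50.8% in DESeq2 and 32.2% in limma-voom. LOC_Os04g13000 and LOC_Os10g33500 were highest in the overexpression libraries, at 6.69 to 45.2 and 18.3 to 25.8 CPM, against at most 0.368 and 1.39 CPM in the CRISPR libraries. LOC_Os01g35330 was at 81.9 to 172 CPM in the CRISPR libraries and at most 3.45 CPM in the others. LOC_Os02g12310 was higher in the CRISPR libraries at both times, with 73.6 and 149 CPM at 72 HAF. Without the 3 overexpression libraries in which reads at the target were not raised, 98 genes passed, 47 of them shared, in a test whose overexpression arm is the OE78 72 HAF library alone and takes its spread from the other lines. In a fit of class and time to the 8 mutant libraries alone, with no term for the line, 15 genes passed. Its error takes in the spread between the lines of a class, which the additive fit leaves out. The 4 libraries of a class come from 2 lines and are not independent. The count was 8 and 6 without OE78 and OE79 72 HAF, 8 and 9 without CR78 and CR79 72 HAF, 59 and 50 without OE78 and OE79 48 HAF, 75 without CR79 48 HAF, and 72 and 63 without WT 48 and 72 HAF.

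Overexpression and CRISPR libraries were also compared within 72 HAF, a contrast added after the data were seen. Of 27 starch synthesis genes 8 were lower in the overexpression libraries and none higher, or 9 and 1 when adjusted over the list alone (camera in limma, adjusted p = 0.000214, and adjusted p = 0.494 with an estimated correlation). Wx had 36.8 and 77.1 CPM in OE78 and OE79, 646 and 525 in CR78 and CR79, and 116 in WT (log2 fold change -3.38, SE 0.362, edgeR adjusted p = 0.0162). SSIIa (log2 fold change -2.21, SE 0.208, edgeR adjusted p = 0.00858), AGPS2 (-1.55, SE 0.199, adjusted p = 0.0205) and the branching enzyme gene BEI (LOC_Os06g51084; -0.94, SE 0.156, adjusted p = 0.0396) were lower as well. SUS3 was the 1 of 8 sucrose cleavage genes that passed (log2 fold change -1.75, SE 0.295, edgeR adjusted p = 0.042), with 2 lower when adjusted over the list alone (camera in limma, adjusted p = 0.0119, and adjusted p = 0.396 with an estimated correlation). Of 7 storage protein genes 2 were lower, or 7 when adjusted over the list alone, the doubtful LOC_Os03g55730 among them (camera in limma, adjusted p = 1.57e-05, and adjusted p = 0.24 with an estimated correlation). Of 6 endosperm transcription factors 1 was lower, or 5 when adjusted over the list alone (camera in limma, adjusted p = 1.08e-07, and adjusted p = 0.234 with an estimated correlation). Both CRISPR libraries lay above the other 3 libraries of 72 HAF in 13 of 27 starch, 6 of 7 storage protein and 6 of 6 transcription factor genes. They lay below them in 2, 0 and 0. A random order gives 10% for a single gene, but members of a list are not independent, so 10% is no yardstick for these counts. At 48 HAF both CRISPR libraries lay above the other 3 in 4 starch genes and below them in 7.

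**Figure D3:**
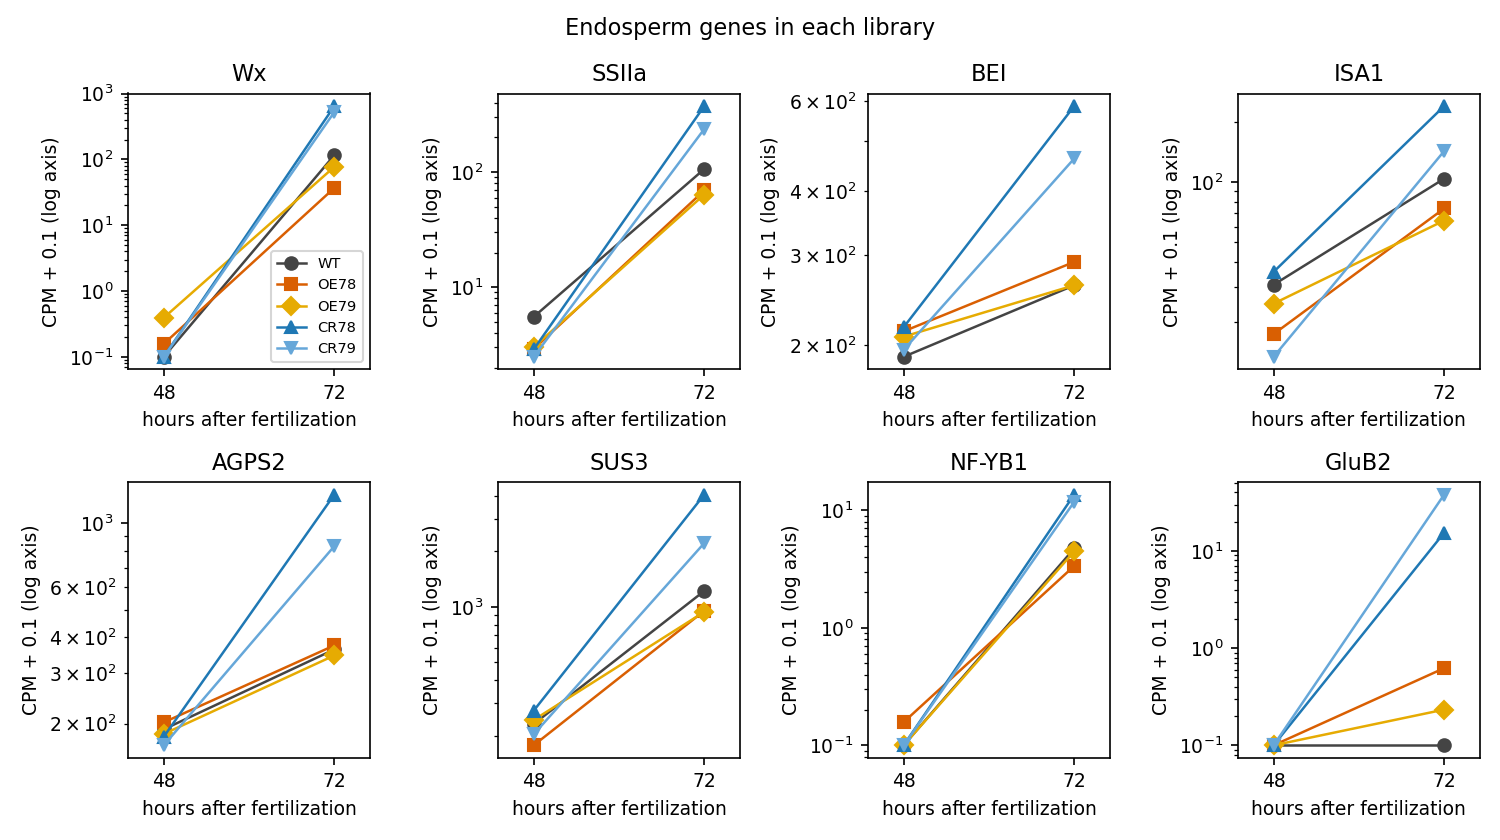
Expression (CPM + 0.1 on log vertical axes) of Wx, SSIIa, BEI, ISA1, AGPS2, SUS3, NF-YB1 and GluB2 at 48 and 72 hours after fertilization (horizontal axes), with a line for each genotype. At 72 HAF the CR78 and CR79 libraries lie above those of WT, OE78 and OE79 for each of these genes, with Wx at 646 and 525 CPM against 36.8 to 116 CPM.

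Other genes set the classes apart at 72 HAF in the opposite direction. ABA8ox1 (LOC_Os02g47470) and ABA8ox3 (LOC_Os09g28390), hydroxylases that break down abscisic acid, were higher in the overexpression libraries (log2 fold change 2.95, SE 0.543, edgeR adjusted p = 0.0497, and 2.53, SE 0.42, edgeR adjusted p = 0.0396), 2 of the 7 genes of their list and 3 higher against 1 lower when adjusted over the list alone (camera in limma, adjusted p = 0.0534). Against the 1 WT library of 72 HAF, the CRISPR libraries departed further than the overexpression libraries for this list. Over its 5 members whose names passed the check, the median log2 fold change was -1.917 in CRISPR and 0.134 in overexpression libraries. Type II MADS genes had no member past the threshold but 7 of 18 higher in the overexpression libraries when adjusted over the list alone (camera in limma, adjusted p = 1.61e-05, and adjusted p = 0.24 with an estimated correlation). Of 16 replication genes none passed and 6 were higher when adjusted over the list alone (camera in limma, adjusted p = 0.0129, and adjusted p = 0.494 with an estimated correlation). MET1b (LOC_Os07g08500), a maintenance DNA methyltransferase, was lower in the overexpression libraries, at 26.6 and 26.5 CPM against 51.8 and 56.6 in CR78 and CR79 (log2 fold change -1.04, SE 0.163, edgeR adjusted p = 0.0345). Cell wall synthases (adjusted p = 0.0374) and gibberellin genes (adjusted p = 0.0465) were shifted up and auxin synthesis genes down (adjusted p = 0.0255) by camera in limma, with no member past the threshold over all genes and, adjusted over the list alone, 1 cell wall gene higher and 2 auxin synthesis genes lower. With an estimated correlation these gave adjusted p = 0.494, adjusted p = 0.403 and adjusted p = 0.24. Pericarp markers gave camera adjusted p = 0.804 (limma) and heat shock genes 0.629.

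In all, 129 genes were higher and 112 lower in the overexpression libraries at 72 HAF (edgeR), and 4196 had an unadjusted p under 0.05. The balance depended on the tool: 53.5% of the genes were higher here, 22.6% in limma-voom and 67.7% in DESeq2. At 48 HAF 1 gene passed, LOC_Os10g33500, which was higher in the overexpression libraries, with 1822 at an unadjusted p under 0.05 in edgeR, 103 genes in DESeq2 and 0 in limma-voom. There the replication genes were shifted up in the overexpression libraries with no member past the threshold, also when adjusted over the list alone (median log2 fold change 0.34, camera in limma, adjusted p = 4.74e-06, and adjusted p = 0.804 with an estimated correlation). Photosynthesis (adjusted p = 0.00223) and heat shock genes (adjusted p = 0.0191) were shifted down by camera in limma, both at adjusted p = 0.804 with an estimated correlation and with no member past the threshold over all genes. Each shift rests on 1 CRISPR library, since among the 48 HAF libraries every tested photosynthesis gene was highest in CR79 and every tested heat shock gene in CR78. The 72 HAF count was 0 without OE78 72 HAF, 20 without OE79 72 HAF, 115 without CR78 72 HAF, 25 without CR79 72 HAF, and 428 and 423 without OE78 and OE79 48 HAF, and at 48 HAF it was 0 without CR78 48 HAF.

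The WT arm at 72 HAF is 1 library, so tests against it take its spread from the other groups and leave its own unmeasured. Against it, 1 gene passed for the CRISPR and 1 for the overexpression libraries (edgeR), in both cases LOC_Os10g11100, higher than in WT by 4.40 and 4.56 on the log2 scale and named after its values were seen, with 2596 and 1177 at an unadjusted p under 0.05, and 259 and 43 genes in DESeq2. In limma-voom LOC_Os10g11100 did not pass, and the count was 1, another gene, for the CRISPR and 0 for the overexpression libraries. In the CRISPR libraries no list member passed over all genes. Adjusted over the list alone, 8 starch synthesis genes, 6 endosperm transcription factors and 5 storage protein genes were higher than in WT (camera in limma, adjusted p = 8.65e-07, 1.85e-08 and 0.000109). With an estimated correlation these were adjusted p = 0.659, adjusted p = 0.179 and adjusted p = 0.323. Storage genes lay above WT in the overexpression libraries as well. Over the 5 whose names passed the check, the median log2 fold change was 4.147 there and 8.634 in the CRISPR libraries. GluB2 had no read in WT 72 HAF, so the size of such a difference depends on the prior count. Replication genes of the overexpression libraries had a median of 0.26 against WT (camera in limma, adjusted p = 0.00152, and adjusted p = 0.985 with an estimated correlation), and type II MADS genes 0.33 (adjusted p = 2.46e-06, and adjusted p = 0.985 with an estimated correlation). Cell wall synthases were shifted down (adjusted p = 0.015) and auxin synthesis genes up (adjusted p = 0.0367) in the CRISPR libraries by camera in limma, at adjusted p = 0.659 and adjusted p = 0.323 with an estimated correlation, and 2 auxin synthesis genes were higher when adjusted over the list alone. Without OE78 or OE79 72 HAF 2 genes passed for the CRISPR libraries. Without CR78 or CR79 72 HAF the counts were 43 and 2, where 1 library stands against 1 and both are assumed to vary like the other groups. For the overexpression libraries the count was 2 without WT 48 HAF.

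Whether the change from 48 to 72 HAF differed between the classes was tested as an interaction. The interaction, taken as the signed change in the overexpression minus that in the CRISPR libraries, was positive for 3 genes and negative for none (edgeR), with 2565 at an unadjusted p under 0.05. LOC_Os01g50910 rose from 29.4 to 46.5 CPM in OE78 and from 35.9 to 52 in OE79, and fell from 69.5 to 7.65 in CR78 and from 63 to 5.39 in CR79 (interaction log2 fold change 3.91, SE 0.268, edgeR adjusted p = 0.00509). LOC_Os04g45340 had the same order (5.22, SE 0.497, edgeR adjusted p = 0.0335), and LOC_Os04g56995 fell in all these lines, further in CR78 and CR79. No list member passed. The count was 123 without OE79 48 HAF, 0 without OE79 72 HAF, 12 without CR78 72 HAF, and 1 without OE78 48 HAF, OE78 72 HAF or CR78 48 HAF. This fit does not use that each line gave both libraries. With the line as a block the count was 1018, of which 845 were positive and 173 negative, with 8 of 27 starch and 3 of 8 sucrose cleavage genes negative. The block fit has fewer residual degrees of freedom and was not run on simulated data.

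The contrasts OE78 minus CR78 and OE79 minus CR79 share no library. Their log2 fold changes correlated across the 25354 genes with Pearson r = 0.201, and 56.1% of genes had the same sign. Genes are not independent replicates, so no p is given. Within 48 HAF r was 0.07 and within 72 HAF 0.438.

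The stage index rose by 5.71 from WT 48 to WT 72 HAF, the libraries its genes were chosen in, so the other libraries are expected to lie between the WT values. At 72 HAF it was 3.70 and 3.68 in CR78 and CR79, 2.48 in WT, 1.82 in OE78 and 1.19 in OE79. At 48 HAF WT was at -3.23 and the mutant libraries lay between -2.49 and -1.75. The overexpression libraries under WT at 72 HAF therefore give no evidence of an earlier stage, while the CRISPR libraries lie outside the WT values. The overexpression minus CRISPR difference was -1.22 over both times, -2.18 at 72 HAF and -0.26 at 48 HAF, given as values with no test.

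**Figure D4:**
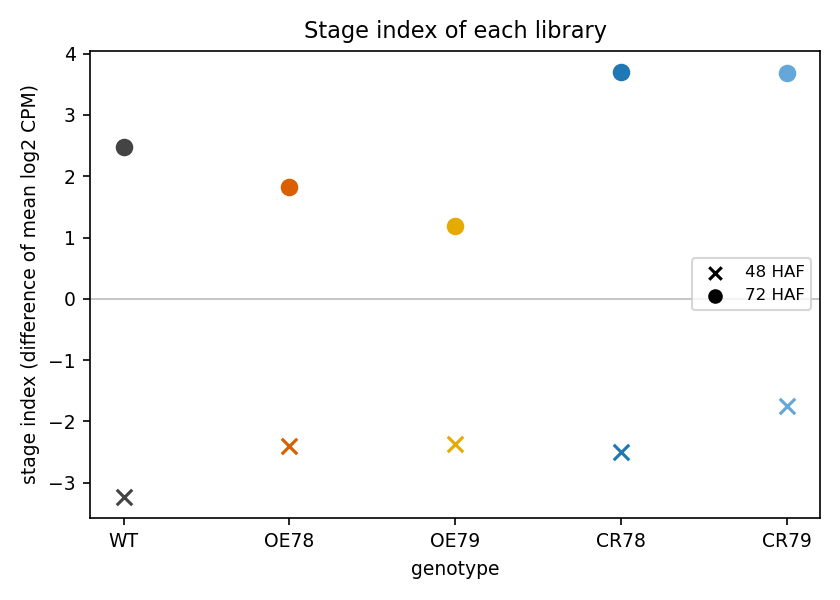
Stage index (vertical axis, difference of mean log2 CPM between genes that rose and genes that fell in WT) of each library by genotype (horizontal axis), with crosses for 48 and filled circles for 72 hours after fertilization. At 72 HAF both CRISPR libraries (3.70 and 3.68) lie above WT (2.48), and the libraries labelled OE78 and OE79 (1.82 and 1.19) lie under it. At 48 HAF all mutant libraries lie above WT (-3.23).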

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

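The swap test, the test of genes shared by both OE78 libraries, the share of counts outside the most abundant genes and the spread of the switched-on genes were chosen only after the results were seen, as were the contrast within 72 HAF and the list tests with the line as a block.

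A different course of the classes between the times was found by the interaction test in edgeR for 3 genes. That fit leaves out that each line gave both libraries, and with the line as a block, planned before the data were seen, 1018 genes passed, with fewer residual degrees of freedom. The interaction log2 fold change was 3.91 for LOC_Os01g50910, 5.22 for LOC_Os04g45340 and 2.39 for LOC_Os04g56995. By camera in limma 4 lists passed, with median interactions of 0.46 for type II MADS genes (adjusted p = 2.61e-05), -0.135 for starch synthesis (adjusted p = 0.00257), -0.845 for sucrose cleavage (adjusted p = 0.00699) and -4.04 for storage proteins (adjusted p = 0.00546). With an estimated correlation these gave adjusted p = 0.421, adjusted p = 0.614, adjusted p = 0.421 and adjusted p = 0.421. No member passed over all genes, and adjusted over the list alone 2 type II MADS, 8 starch and 2 sucrose cleavage genes did. With the line as a block, 7 lists passed, these 4 among them, and with an estimated correlation none of the 7 did (adjusted p = 0.385 to adjusted p = 0.684). Over all genes 8 starch, 3 sucrose cleavage and 1 chromatin gene were then negative, and 3 abscisic acid turnover, 2 heat shock, 1 type II MADS and 1 cell wall gene positive. The heat shock list was among the 7 (adjusted p = 6.08e-05, and adjusted p = 0.475 with an estimated correlation), and its values stand out in CR78 48 HAF alone. Of the 7 storage genes 3 had no read at 48 HAF, so the size of their interaction depends on the prior count.

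MADS78 was read 2116 times in 1 of the 2 libraries labelled OE78 and 6 times in the other. If seeds of the line had raised MADS78 at 48 HAF, a swap with another 48 HAF library would leave over 100 reads elsewhere. The highest count among the other 4 was 6. Raised reads were seen at 72 HAF alone, so without that assumption the counts cannot decide on a swap. Whether the OE78 48 HAF library comes from the line of the OE78 72 HAF library stays open. The correlation of their deviations from the mean of each time was 0.065 and was higher, at 0.169, with CR79 72 HAF, while each of the other 4 libraries of 48 HAF correlated best with its own line. Genes at least 4-fold above the 6 libraries of 3 other lines in both OE78 libraries, such as LOC_Os03g18779 at 74.2 and 76.2 CPM, numbered 3 to 8 by the lines taken, against 0 to 3 in the 20 pairs of different lines, so the ranges meet. With WT, OE79, CR78 or CR79 left out, the OE78 pair gave 3, 6, 5 and 8 genes. Pairing OE78 48 HAF with the 72 HAF library of the line left out gave 0, 2, 2 and 3. In each of these pairings the OE78 pair had more. LOC_Os06g43150 stood at 75.5 and 58.3 CPM in the OE78 libraries and at most 0.675 CPM in any other library. LOC_Os07g24950 stood at 3.33 and 1.5 CPM there and at 0 elsewhere. These genes and counts point to 1 line for both libraries, while the correlation does not. Seeds of the line without an active transgene could give the MADS78 counts, which was not tested.

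Of 27 starch synthesis genes 8 were lower in overexpression than in CRISPR libraries at 72 HAF, and the list test (camera in limma, adjusted p = 0.000214) gave adjusted p = 0.494 with an estimated correlation. A few abundant genes taking the counts are argued against: the share of counts outside the 50 most abundant genes differed by 0.062 on the log2 scale and was higher in the overexpression libraries, whereas the 8 genes were lower there, with log2 fold changes of -0.938 to -3.376. The test planned for this, leaving out those 50 genes, moved nothing (a median of -0.377 before and after, over the 25 starch genes left) and decides nothing. A larger share of endosperm RNA in the CRISPR libraries stays open, as the genes switched on between the times cannot decide it. All 133 of them were higher there. They were picked by the time effect over all 10 libraries, which favours genes high in the CRISPR libraries at 72 HAF. Their log2 ratios had an interquartile range of 1.33, against 1.41 between the overexpression and 0.674 between the CRISPR lines. The first range compares means of 2 libraries and the others single libraries, which tends to narrow the first. CRISPR seeds further along the wild-type course also stay open: the log2 ratios of CRISPR over overexpression correlated with the WT change at 0.454 across genes at 72 HAF, and at 0.137 at 48 HAF. An effect of the manipulated genes stays open beside these and was not tested apart from them.

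For the time effect, 100 splits of the 10 libraries into groups of 5 were drawn. As many genes were found in 1 split alone, the real one, with 7114 genes against 541 in the next. The 541 came from splits that part WT, CR78 and CR79 by time, so they carry the time effect itself. Splits other than the real one leave time in the spread, which lowers their counts. The comparison therefore cannot decide on chance. Only 13 of the drawn splits part all 5 genotype pairs, as the real one does. The others among these 13 gave 0 genes, but 13 splits are too few to exclude chance by this count. For overexpression against CRISPR, 34 splits of the 8 mutant libraries could be fitted with time as a term. The real one, with 15 genes, was the 1 split with as many, against 10 in the next. The latter joins overexpression at 48 HAF with CRISPR at 72 HAF. With time as a term it is the class by time interaction and no measure of chance. Only 3 of those splits keep the lines whole, too few to exclude a chance difference between lines.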

How the results depend on the processing

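The contrasts within 72 and 48 HAF, the run without the CR78 and OE78 48 HAF libraries, the run without the 3 overexpression libraries without raised reads of the target, the lists of checked members only and the interaction lists with the line as a block were chosen after seeing the data. No gene named as past the threshold changed sign, but the balance of higher and lower calls turned in places. In overexpression against CRISPR, 37.2% were higher in the main test, 50.8% in DESeq2, 53.3% in the 8 mutant libraries alone and 18.7% to 62.5% without each library. At 48 HAF the 1 gene was higher, and 36.3% were without a filter, 35% in DESeq2. For CRISPR against WT at 72 HAF, 42.4% were higher without a filter. DESeq2 size factors in edgeR and leaving out the 50 most abundant genes kept all 11 gene counts within 1.5 times and moved no share of higher calls by over 10 percentage points. The libraries are paired by line: time gave 6255 genes without the genotype as a block, and the labels carry no replicate numbers to pair by. The cause of the shifts was not tested, except that runs with fewer libraries have less to test with.

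For time (7114 genes), 2765 passed with at least 2-fold change, 2388 without the CR78 and OE78 48 HAF libraries and 4386 without genotype CR78. Leaving out each library gave 4388 to 5835. The other gene counts depended on the filter and the tool. Without a filter, edgeR gave 106 genes for OE78 (36 in the main test), 85 for OE79 (39), 100 for CR78 (19), 1059 for CR79 (555), 642 for overexpression against CRISPR (145), 432 at 48 HAF (1), 2061 at 72 HAF (241), 1003 for the interaction (3), 905 for CRISPR (1) and 150 for overexpression (1) against WT at 72 HAF. DESeq2 in the same order gave 131, 108, 95, 1209, 792, 103, 1230, 542, 259 and 43. Limma-voom gave 20 for OE78, 52 for CR78, 401 for overexpression against CRISPR, 0 at 48 HAF, 1 for the interaction and 0 for overexpression against WT at 72 HAF. At 72 HAF, 53.5% of the genes were higher in the overexpression libraries in the main test, 22.6% in limma-voom, 67.7% in DESeq2, 65.9% without a filter and 25% to 67.8% without each library. An arm left with 1 library is assumed to vary like the other groups. With only the 4 libraries of the genotypes compared, 70 genes passed for OE78 and 135 for CR78. CR79 had 332 with at least 2-fold change, overexpression against CRISPR 15 in the 8 mutant libraries alone, and the interaction 1018 with the line as a block, with 7 lists against 4, none of which passed with an estimated correlation.

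Leaving out each library gave 5 to 36 for OE78, 2 to 36 for OE79, 2 to 27 for CR78, 7 to 283 for CR79, 6 to 110 for overexpression against CRISPR, 0 to 1 at 48 HAF, 0 to 428 at 72 HAF, 0 to 123 for the interaction, 1 to 43 for CRISPR and 1 to 2 for overexpression against WT at 72 HAF. The correlation of 0.201 was 0.206 at 10 CPM or more, 0.07 at 48 HAF, 0.438 at 72 HAF and 0.177 by Spearman's method. The stage difference of -1.22 was -1.71 with 50 and -0.87 with 500 genes each way. With an estimated correlation 0 lists passed in any contrast, from 7 for time, 3 for OE78, 2 for OE79, 6 for CR78, 5 for CR79, 8 for overexpression against CRISPR, 4 for the interaction, 3 at 48 HAF, 9 at 72 HAF, and 5 and 2 for CRISPR and overexpression against WT at 72 HAF. With checked members only, 3 lists passed for time, 3 for CR79, 3 for overexpression against CRISPR, 7 for the interaction and 3 for CRISPR against WT at 72 HAF. Of the 62 genes named or listed for time, 57 still passed in DESeq2 and 62 in limma-voom, and of 9 at 72 HAF 8 and 6 did, 0 without OE78 72 HAF. Depth was similar in 9 libraries, and genes near 0 reads, such as MADS78 in WT, are limited by it.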

Other observations

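The overlaps, the counts of genes shared within a line and the values chosen below were picked only after the results were seen.

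Heat shock genes stood out in CR78 48 HAF alone. HsfA2a (LOC_Os03g53340), a heat stress transcription factor, was at 128 CPM there and at 0.336 to 13.1 CPM in the other libraries. HSP17.4 (LOC_Os03g16030), a small heat shock protein gene, was at 91.2 CPM against 4.4 to 15.4, and HSP26.7 (LOC_Os03g14180) at 20.6 CPM against 0.39 to 7.22. CR78 72 HAF had 9.6 CPM of HSP101, the lowest of the 10 libraries.

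Genes that set the classes apart at 72 HAF were largely genes that changed with time. Of the 112 genes higher in the CRISPR libraries, 89 rose and 1 fell with time, and of the 129 higher in the overexpression libraries 66 fell and 0 rose. Both comparisons use the same libraries, so the overlap is a description. On the first principal component, with 55.6% of the variance, CR78 and CR79 72 HAF were at 110.8 and 118.4, WT at 53.3, OE78 at 43.7 and OE79 at 31.7.

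Each line had genes of its own at both times. At least 4-fold above the other 8 libraries stood 3 genes in OE78, 6 in OE79, 3 in CR78 and 8 in CR79. WT had 0 such genes, and 5 at least 4-fold below all mutant libraries. LOC_Os03g02470 is one, at 0.059 and 0 CPM in WT, 6.54 and 7.09 in OE79 and 158 to 230 in the other mutant libraries. LOC_Os10g30240 was at 103 and 82.4 CPM in OE79 and at most 0.201 CPM elsewhere.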
